A study of Mus musculus with 4 samples.

How the data were processed

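Regulatory T (Treg) cells from visceral adipose tissue (VAT) of male mice were profiled by droplet-based single-cell RNA sequencing with a 5′ chemistry, in which each captured RNA molecule carries a unique molecular identifier (UMI). Cells of each condition were labelled with an oligonucleotide-tagged antibody (a hashtag) before the conditions were mixed, so that each droplet can be assigned to its condition. There were 2 separate experiments. In the Srebf2 pool, Hashtag 1 marked cells of 4 mice with intact Srebf2 (WT) and Hashtag 2 cells of 4 mice with floxed Srebf2 and a Cre recombinase driven by Foxp3 (KO). In the diet pool, Hashtag 3 marked cells of 5 mice on normal chow (NCD) and Hashtag 4 cells of 5 mice on a high-fat diet (HFD) for 22 weeks. Cells were sorted as live CD3+ CD4+ Foxp3+ before mixing, per the labels.

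The deposited matrices hold raw UMI counts per gene and cell, with the hashtag counts as further rows of the same matrix, per the file headers. The matrix header names Cell Ranger 7.1.0 for the Srebf2 pool and 7.0.1 for the diet pool, whereas the submitters' processing notes name version 7.0.1 and the mm10 build for both. The matrices held 9036 and 11456 barcodes, each with at least 500 UMIs, over 32285 gene rows. Filters applied by the authors beyond the counting software's own cell calling are not given in the sources used here. Antigen receptor sequences of single cells were not used here, and no deposited annotation of cell types was used.

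Hashtags were called with HTODemux of Seurat 5.3.0 at a positive quantile of 0.99. This left 3843 WT and 4035 KO singlets, with 504 barcodes positive for both hashtags and 654 for neither, and 4930 NCD and 4982 HFD singlets, with 580 positive for both and 964 for neither. Cells with 500 or more genes and under 10% mitochondrial counts were kept. Droplets with both hashtags were removed as doublets. With conditions mixed 1:1, about as many droplets should hold a pair of cells of the same condition (505 and 580), and hashtags cannot find these. Scrublet scores marked 0 of 7795 and 1 of 9788 cells, so that caller did not work here and doublets within a condition remain.

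Cells of each pool were clustered in scanpy 1.11.5 (Leiden, resolution 0.6, 15 neighbours) on 30 principal components of 2000 variable genes. Genes of cholesterol synthesis and sterol uptake, antigen receptor, immunoglobulin, mitochondrial and ribosomal genes were left out of the variable genes. Clusters were named from marker lists, and each name is written as "-like" because it was rebuilt from these lists. A cluster was taken as another cell type when its Foxp3 level was below 60% of the pool's and 3 or more markers of that type reached 20 counts per 10⁶ (CPM) and stood at least 4-fold above the median cluster. Among the remaining clusters, a class named a cluster when its markers lay highest between their lowest and highest cluster and no other class came close. A cluster with more markers of another class than of its own among its 10 leading genes stayed unnamed. The rule that turns markers into names went through 5 versions after the clusters had been seen, so the shares of unnamed clusters are given beside the named ones. Clusters of other cell types were left out of the sums.

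Raw counts were summed over the Treg cells of each condition and expressed as CPM, the counts per 10⁶ of the summed total. Each log2 ratio sets KO against WT or HFD against NCD, with 0.5 counts added to each sum. Each condition was a single pool of mice with a single hashtag. There is therefore 1 sample per condition, no replicate check and no test, and no p-value is given. Levels carry exact Poisson intervals, ratios exact intervals from the binomial split of the summed counts, and shares of cells exact binomial (Clopper-Pearson) intervals, all at 95%. These intervals cover counting error only and leave out the spread between mice and sorts. Depth was 14648592 UMIs in WT, 16261836 in KO, 20008586 in NCD and 19087584 in HFD Treg cells.

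The marker and gene lists, the rule for naming genes and the alternatives below, save those said to be added, were set before the data were examined. Per comparison the rule for genes took the 12 highest and 12 lowest log2 ratios among genes at 20 CPM or more in the higher condition, the 6 highest and 6 lowest within ST2-high-like cells, Srebf2, Foxp3, Il1rl1 and Pparg, and up to 4 members of each gene list at 5 CPM or more that lay farthest from equal levels. Antigen receptor segments and immunoglobulin genes were described apart, and several genes that the rule takes are left out of the text. A gene was counted as higher or lower in size at 1.25-fold or more, which is a rule of size and not a test. For 23 gene lists the median log2 ratio of the members at 5 CPM or more was set against 10000 random lists of the same size matched on mean expression. The percentile among these describes these pools and is not a p-value, and the interval of a median comes from 1000 Poisson redraws of the counts. The ratios of both comparisons were correlated across genes at 20 CPM or more. Genes are not independent replicates, and the experiments share no mice and no control libraries.

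Gene positions were taken from an annotation table of the GRCm38.p6 assembly, matched on gene symbols. Apobec3 and Cbx7 overlap on chromosome 15, and Gm42418 and Cmss1 share reads, so the split of counts between such genes is uncertain.

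Ratios, intervals, list medians and reweighting were tested on simulated sums drawn as Poisson counts, with 200 of 6263 genes changed by known folds in each comparison. Such draws hold no excess spread between cells, so the coverage of the intervals is checked for counting error only. For KO against WT, genes set to a log2 ratio of −2, −1, 1 and 2 came back at medians of −2.01, −0.99, 1.01 and 2.01, with the true value inside the interval for 92, 90, 96 and 98% of them. For HFD against NCD the medians were −2.00, −0.99, 0.99 and 2.00, with 94, 96, 96 and 96% inside. A simulated change in the mix of clusters gave a mean absolute log2 ratio of 0.39 in both comparisons before reweighting, and 0.07 for KO against WT and 0.06 for HFD against NCD after it. The simulated clusters had known labels and ample counts in both conditions, whereas some clusters of the diet pool came almost wholly from 1 condition.

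Alternatives covered other hashtag calls (a fixed share of 90% or a mixture model), other minimum numbers of genes (200 or 1000), a mitochondrial limit of 5%, removal of Scrublet calls, all singlets kept, TMM scaling (edgeR 4.0.16), median-ratio size factors (DESeq2 1.42.0), totals without mitochondrial, ribosomal and receptor genes, the mean of per-cell CPM, clusters reweighted to the same shares, other expression minimums, other clustering resolutions, clustering without genes differing 1.5-fold, and the share of cells with an Il1rl1 UMI after every cell was thinned to 2000 UMIs. Clustering without the dissociation and early response lists, and naming clusters by mean marker ratio, were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9, igraph 0.11.9 and R 4.3.3 were used.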

Results

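VAT Treg cells are the Foxp3-expressing T cells that reside in visceral fat, where a large part of them carries ST2, the receptor for interleukin-33 (gene Il1rl1). The Srebf2 pool held 3644 WT and 3901 KO Treg cells from 25-week-old mice, with medians of 3588.5 and 3664 UMIs per cell. The diet pool held 4402 NCD and 4633 HFD Treg cells from mice aged 23 to 27 weeks, with medians of 4017 and 3196 UMIs. A Foxp3 UMI was found in 55.4% of WT, 57.2% of KO, 54.4% of NCD and 40.6% of HFD cells. Another 157 WT, 93 KO, 496 NCD and 257 HFD cells fell into clusters of other cell types and were left out. Each condition is 1 pool of mice, so every difference below lacks a replicate check.

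The first comparison asked how Treg cells differ when Srebf2 is deleted in Foxp3-expressing cells. Srebf2, which encodes SREBP2, the transcription factor that drives cholesterol synthesis, stood at 65.7 CPM (95% interval 61.7 to 70.0) in WT and 3.94 CPM (3.03 to 5.03) in KO cells, 16.6-fold lower. Genes of cholesterol synthesis were lower with it, at a median log2 ratio of −0.71 (counting interval −0.82 to −0.59), with 16 of 19 measured members lower by the rule of size and 0 higher. Genes of resting, lymphoid-homing Treg cells were higher in KO (median 0.58, 0.34 to 0.64), as were genes of the type 1 program led by Ccl5, Nkg7 and Cxcr3 (median 0.30, 0.24 to 0.43). ST2-high-like cells made up 74.4% of WT Treg cells (72.9 to 75.8) and 53.7% of KO Treg cells (52.1 to 55.2). Counted by an Il1rl1 UMI after thinning, the shares were closer, at 59.0% and 48.3%.

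Srebf2 (ENSMUSG00000022463) lies on chromosome 15 from 82147269 to 82205379 in GRCm38.p6. The sequenced tags lie near transcript starts, and which exons are floxed is not given in the sources used here, so the fall in counts checks the hashtag labels without measuring how much of the transcript is lost. Of the 64 Srebf2 UMIs left in KO cells, 49 were in resting Treg-like cells, where the log2 ratio was −2.27 (−2.80 to −1.78), against −5.35 (−6.28 to −4.64) in ST2-high-like cells.

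The median of the cholesterol synthesis list in KO lay below all 10000 matched random lists (percentile 0). Squalene epoxidase (Sqle) was at 16.4 CPM in WT and 0.676 CPM in KO (log2 ratio −4.54). Idi1, the isopentenyl diphosphate isomerase, was at 34.1 and 8.42 CPM (−2.01), and Cyp51, the lanosterol demethylase, at 25.6 and 9.04 CPM (−1.50). The 3 members that differed by less than that rule, looked up after their values were seen, were Acat2 (−0.23), Pmvk (−0.05) and Ebp (0.05). Within classes the list median was −0.64 (−0.83 to −0.56) in ST2-high-like, −0.69 (−1.02 to −0.48) in resting Treg-like and −0.56 (−1.03 to −0.45) in CXCR3 Treg-like cells.

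Of the sterol uptake and SREBP control list, 5 of 11 members were lower in KO and 0 higher (median −0.23, percentile 0.05). Besides Srebf2, these included Tmem97 (−1.46) and Insig1 (−0.62), which retains SREBP precursors in the endoplasmic reticulum. Of fatty acid synthesis and desaturation genes, 4 of 7 were lower and 0 higher (median −0.34, percentile 0.01): Acsl3 was at −1.74, acetyl-CoA carboxylase Acaca at −0.67, Elovl6 at −0.35 and fatty acid synthase Fasn at −0.34. By class this median was −0.32 (−0.48 to −0.00) in ST2-high-like, −0.66 (−1.03 to −0.28) in CXCR3 Treg-like and −0.00 (−0.25 to 0.18) in resting Treg-like cells, and it was 0.01 in cluster 3 of the ST2-high-like cells. Sterol efflux and LXR target genes had a median of −0.13 (percentile 1.28), with Soat1 at −0.45, Mylip at −0.42 and Smpdl3a at 0.34. The isoprenoid branch (median 0.05, percentile 85.8), in which Icmt was at 0.37 and Pdss1 at −0.26, and fatty acid uptake, storage and oxidation genes (median −0.02, percentile 27.0), in which Dgat2 was at 0.70 and Cpt1a at 0.42, showed no common direction.

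Of the resting and lymphoid-homing list, 6 of 11 members were higher in KO and 0 lower (percentile 100). The homing receptor Ccr7 was at 13.0 CPM in WT and 23.9 CPM in KO (0.87), and Bach2 and Satb1 were at 0.85 and 0.65. Of the type 1 program, 5 of 10 members were higher and 1 lower (percentile 100). The chemokine Ccl5 was at 278 and 696 CPM (1.33), the cytotoxic granule gene Nkg7 at 69.4 and 147 CPM (1.09), Cxcr3 at 69.3 and 126 CPM (0.86) and Tbx21, which encodes T-bet, at 0.83. The Treg core list was at 0.17 (percentile 100), with Izumo1r at 0.41 and Il2rb at 0.33, while Foxp3 was at 252 CPM in WT and 264 CPM in KO. Inhibitory receptors had a median of 0.23 (percentile 100), with Lag3 at 1.02 and Entpd1 at 0.34. Chemokine receptors (median 0.11, percentile 99.2) included both Ccr3 at −0.95 and Ccr6 at 0.94. Of the IL-2, IL-33 and common gamma list (median −0.01, percentile 28.9), Stat5a was at 0.71 and Stat5b at 0.58.

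The ST2-high adipose Treg signature had a median of −0.20 (−0.23 to −0.15, percentile 0). Il1rl1 was at 697 CPM in WT and 567 CPM in KO (−0.30), Klrg1 at −0.37, Fgl2 at −0.36 and Pparg, the adipose Treg transcription factor, at −0.22, whereas Gzmb was at 0.61. Dissociation and heat shock genes moved with the condition as well (median −0.22, percentile 0), with Atf3 at −0.48, Hspa1b at −0.44 and Fos at −0.39. The remaining lists had medians nearer to 0: antigen receptor early response 0.02 (percentile 60.8; Nr4a2 at 0.39, Cd69 at −0.32), interferon response 0.05 (percentile 79.0; Ifit2 at 0.33, Bst2 at −0.19), proliferation 0.12 (percentile 99.5; Hmgb2 at 0.27), apoptosis 0.08 (percentile 96.7; Bcl2l11 at 0.53), unfolded protein and amino acid stress −0.11 (percentile 0.69; Sdf2l1 at −0.28), glycolysis 0.02 (percentile 64.5; Gapdh at 0.13), nuclear oxidative phosphorylation genes 0.00 (percentile 36.8; Ndufa4 at 0.26), mitochondrially encoded genes 0.02 (percentile 70.6; mt-Nd1 at −0.12) and effector cytokines −0.00 (percentile 49.0; Il13 at −0.86, Ifng at 0.65).

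Among single genes, Apobec3, a cytidine deaminase that restricts retroviruses, was at 220 CPM in WT and 27.0 CPM in KO (−3.02). It overlaps Cbx7 on the genome, and the latter was at −1.13. Catspere2 (−2.00) and Pxdc1 (−1.18) were also among the lowest. The haemoglobin genes Hbb-bt (−2.84), Hbb-bs (−2.46), Hba-a2 (−1.90) and Hba-a1 (−1.71) and the plasma cell gene Jchain (−2.04) were too, but 90% of the WT UMIs of each sat in 2 cells. At the upper end were Penk, the precursor of enkephalins, at 20.2 CPM in WT and 62.8 CPM in KO (1.64), Gramd3 (1.27), Tnfsf8, which encodes CD30 ligand (1.13), Ramp3 (0.96), Trat1 (0.86), Gm8281 (0.86) and Gpm6b (0.84).

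**Figure D1:**
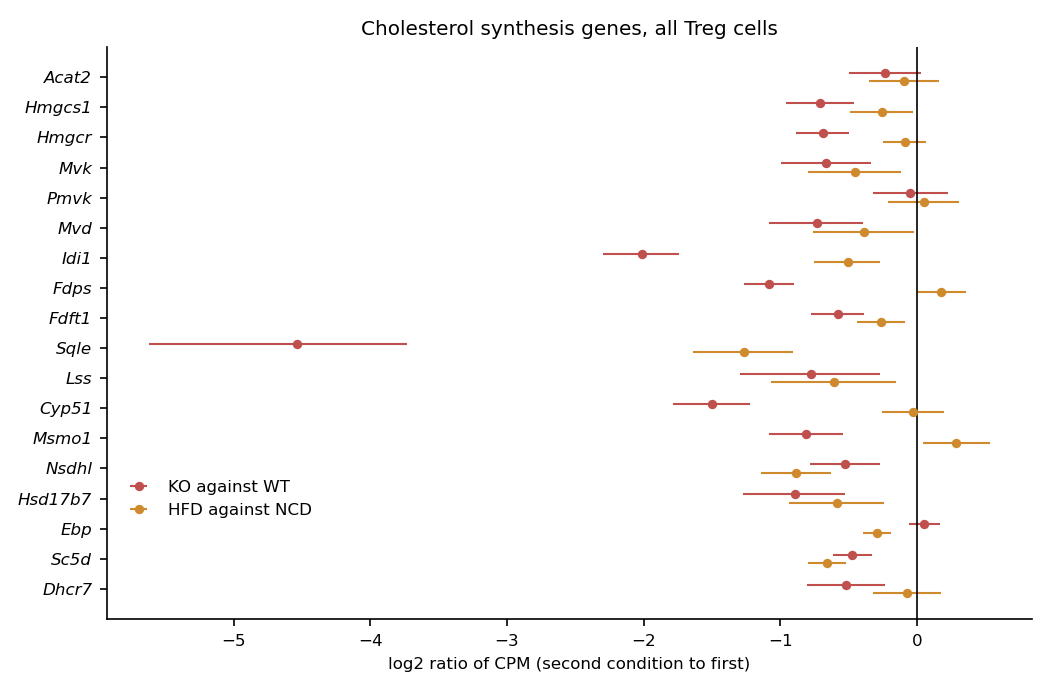
Log2 ratio of CPM for the measured cholesterol synthesis genes but 1, KO against WT in red and HFD against NCD in orange, over all Treg cells, with 95% counting intervals as bars. Sqle lies farthest left of those shown, at −4.54 in KO and −1.27 in HFD.

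Resting Treg-like cells made up 15.6% of WT (14.4 to 16.8) and 29.9% of KO cells (28.5 to 31.4), and CXCR3 Treg-like cells 6.998% (6.19 to 7.87) and 12.9% (11.9 to 14.0). Proliferating Treg-like cells were at 0.796% and 0.872%, and an unnamed cluster led by Il13 and Penk at 2.28% and 2.64%. Of the 3 ST2-high-like clusters, the first was led by the early response genes Atf3, Areg and Nr4a1, the second by Hspa1b, Txnip and Hspa1a, and the third, at 7.74% and 6.72%, by the long genes Mpp7 and Plcl1. With genes that differed 1.5-fold between the conditions left out of the clustering, ST2-high-like cells were at 73.1% and 53.7%, resting Treg-like cells at 16.1% and 30.2% and CXCR3 Treg-like cells at 7.79% and 12.7%. The difference was smaller when every cell was thinned to 2000 UMIs and cells with an Il1rl1 UMI were counted: 59.0% of WT (57.3 to 60.7) and 48.3% of KO (46.69 to 49.97), or 71.1% and 58.9% without thinning. Thinning left out 325 WT and 280 KO cells. B cell-like cells, which may include doublets with Treg cells, gave 14.4% and 12.8% (median depths 6073 and 6990 UMIs).

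Within ST2-high-like cells, Il1rl1 was at 875 CPM in WT and 889 CPM in KO and Pparg at 137 and 145 CPM, and the ST2-high signature had a median of −0.01 (−0.04 to 0.04). Both genes are among the markers that name this class, and all of these markers belong to the signature. Near-equal levels within the class can therefore follow from how its cells were chosen. In CXCR3 Treg-like cells the signature was at −0.27 (−0.35 to −0.13) and Il1rl1 at −0.63 (−0.95 to −0.31), while in resting Treg-like cells the signature was at −0.10 (−0.14 to 0.04) and Il1rl1 at 0.29 (0.10 to 0.49). The highest ratios in ST2-high-like cells were those of Nyap2 (2.20), Tnfsf8 (1.501), Penk (1.47), Gramd3 (1.42), Rbfox1 (1.21) and Cyp11a1 (1.21), an enzyme that cleaves the side chain of cholesterol. The lowest in ST2-high-like cells were those of Srebf2, Apobec3 (−3.04) and the 4 haemoglobin genes. Type 1 program genes had a median of 0.28 (0.23 to 0.44) in ST2-high-like cells, with Nkg7 at 1.07 and Ccl5 at 0.76, and of 0.13 (0.08 to 0.20), 0.14 (0.05 to 0.34) and 0.58 in its clusters 1, 3 and 5. The median was 0.27 (0.20 to 0.48) in CXCR3 Treg-like and −0.09 (−0.25 to −0.01) in resting Treg-like cells, and differences between classes were not tested. Effector cytokines in ST2-high-like cells had a median of 0.39 (0.16 to 0.65), with Ifng at 1.13 and Csf2 at 0.59. Over all KO Treg cells, however, 22.9% of the Csf2 UMIs were in 1 cell. A Csf2 UMI was found in 3.68% of all WT and 2.79% of all KO Treg cells. Markers of conventional CD4 T cells, a list that also holds Ifng, Csf2 and Tnfsf8, had a median of 0.59 (0.47 to 0.84) there and of −0.43 (−0.59 to −0.13) in resting Treg-like cells. Resting genes in ST2-high-like cells had a median of 0.11 (−0.02 to 0.21), although Bach2 was at 0.95. Il10 was at 112 CPM in WT and 164 CPM in KO (0.55). Ccr7 over all cells rests on the choice to leave out other cell types, since its log2 ratio was −0.04 with all singlets kept.

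The second comparison asked how VAT Treg cells of obese mice differ from those of mice on chow. ST2-high-like cells made up 70.6% of NCD Treg cells (69.3 to 72.0) and 4.86% of HFD Treg cells (4.26 to 5.52), and the HFD share reached 23.2% under another clustering. Il1rl1 was at 808 CPM in NCD (795 to 820) and 137 CPM in HFD (132 to 142), and Pparg at 73.9 CPM (70.1 to 77.7) and 8.85 CPM (7.57 to 10.3), or 8.32-fold lower. Genes of resting, lymphoid-homing cells were higher in HFD, at a median log2 ratio of 1.97 (1.89 to 2.05), and so were genes of the interferon response (0.62, 0.51 to 0.86) and of proliferation (1.11, 0.98 to 1.16). The proliferation median was −0.14 with clusters reweighted to the same shares. Cholesterol synthesis genes had a median of −0.29 (−0.41 to −0.20), with 9 of 19 measured members lower by the rule of size and 0 higher. The type 2 cytokines Il5 and Il13 and the growth factor gene Csf2 were lower in HFD by log2 ratios of −4.20, −4.06 and −4.70. Few cells held Csf2 UMIs, 5.34% of NCD and 0.345% of HFD Treg cells. Il5 and Il13 were leading genes of an unnamed cluster with 1.41% of NCD and 0.0863% of HFD cells.

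Of the ST2-high adipose Treg signature, 14 of 16 members were lower in HFD and 2 higher (median −1.93, −2.11 to −1.77, percentile 0). Klrg1 was at 1105 CPM in NCD and 150 CPM in HFD (−2.88) and Il10 at 85.8 and 15.04 CPM (−2.51). Of the chemokine receptor list (median −0.20, percentile 0.95), Ccr1 was at −3.70, Cxcr6 at −3.06 and Ccr3 at −2.93, while Ccr6 was at 2.49. The effector cytokine list had a median of −4.06 (−4.49 to −3.33), with all 5 measured members lower. The IL-2 receptor alpha chain Il2ra was at 667 and 196 CPM (−1.77), Socs2 at −1.96 and Stat5b at 1.58, in a list of IL-2, IL-33 and common gamma genes with a median of −0.12 (percentile 3.13). Foxp3 was at 216 CPM in NCD and 163 CPM in HFD (−0.40), and the Treg core list had a median of 0.31 (percentile 99.6), with Izumo1r at 2.52 and Nrp1 at 1.21.

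Of the resting and lymphoid-homing list, 10 of 12 members were higher and 1 lower (percentile 100). Ccr7 was at 12.6 CPM in NCD and 123 CPM in HFD (3.29) and Tcf7 at 28.9 and 258 CPM (3.15). Inhibitory receptors had a median of 0.66 (percentile 100), with Cd160 at 4.62, Btla at 2.74 and Lag3 at 2.03 but Cd200r1 at −2.16. The type 1 program had a median of 0.02 (percentile 29.4), in which Cxcr3 was at 1.35 and Il18r1 at 1.31 while Il12rb1 was at −1.09. Of interferon response genes, 10 of 13 were higher and 1 lower (percentile 100), with Usp18 at 1.71. Of proliferation genes, 11 of 12 were higher and 0 lower (percentile 100), with Birc5 at 1.52 and Cdk1 at 1.39. In the apoptosis list (median 0.19, percentile 86.9), Fas was at 1.62, Bcl2 at 1.42 and Bcl2l1 at −1.20.

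The cholesterol synthesis median in HFD lay at percentile 0.01 of the random lists. With clusters reweighted to the same shares it was −0.18, at percentile 3.71. Sqle was at 11.2 CPM in NCD and 4.66 CPM in HFD (−1.27), Nsdhl at −0.88 and Sc5d at −0.65. Among sterol uptake and SREBP control genes, 4 of 11 were lower and 0 higher (median −0.26, percentile 0.84), with Srebf2 itself at 67.3 CPM in NCD and 40.2 CPM in HFD (−0.74) and Tmem97 at −0.70. Sterol efflux genes had a median of 0.23 (percentile 87.5): the exporter Abca1 was at 1.499 and 8.12 CPM (2.42) and Abcg1 at 15.6 and 30.7 CPM (0.97), whereas Lpcat3 was at −0.89. The isoprenoid branch was at 0.01 (percentile 25.3), with Rabggtb at 0.48. Fatty acid synthesis genes had a median of −0.17 (percentile 7.20), with Scd2 at 2.45 and Elovl5 at −0.95. Of fatty acid uptake, storage and oxidation genes, 7 of 12 were lower and 2 higher (median −0.42, percentile 0.02), with the lipid droplet coat gene Plin2 at 505 and 54.4 CPM (−3.21), Dgat1 at −0.98 and Dgat2 at 1.21. That median changed sign with clusters reweighted to the same shares (0.08) and with all singlets kept (0.15).

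Dissociation and heat shock genes moved with the diet, with 13 of 14 members lower in HFD and 0 higher (median −1.72, −1.76 to −1.69, percentile 0). Atf3 was at 341 CPM in NCD and 31.4 CPM in HFD (−3.44) and Fosb at −2.74. The antigen receptor early response list had a median of −0.99 (−1.06 to −0.89), with Egr1 at −3.59 and Nr4a1 at −1.89. Glycolysis genes were at 0.35 (percentile 99.6; Hk2 at 2.80), nuclear oxidative phosphorylation genes at 0.19 (percentile 91.4; Ndufa4 at 1.39), mitochondrially encoded genes at 0.25 (percentile 97.4; mt-Cytb at 0.66) and unfolded protein and amino acid stress genes at −0.20 (percentile 3.90; Asns at −0.87). The lowest ratios beyond these lists were those of Wipf3 (−4.61), Fam183b (−4.00), Olfr1259 (−3.92), AA467197 (−3.78), Anxa1, the anti-inflammatory annexin (−3.76), Ptafr (−3.69), Pxdc1 (−3.65), Magi1 (−3.63), Cyp11a1 (−3.62) and 1700061F12Rik (−3.61). The highest were those of Gm49180 (3.91), Dtx1 (3.65), Igfbp4 (3.65), Nsg2 (3.64), Actn1 (3.62), Tbc1d4 (3.46), Ttn (3.44), Rflnb (3.42), Lrig1 (3.31) and Iigp1 (3.28).

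**Figure D2:**
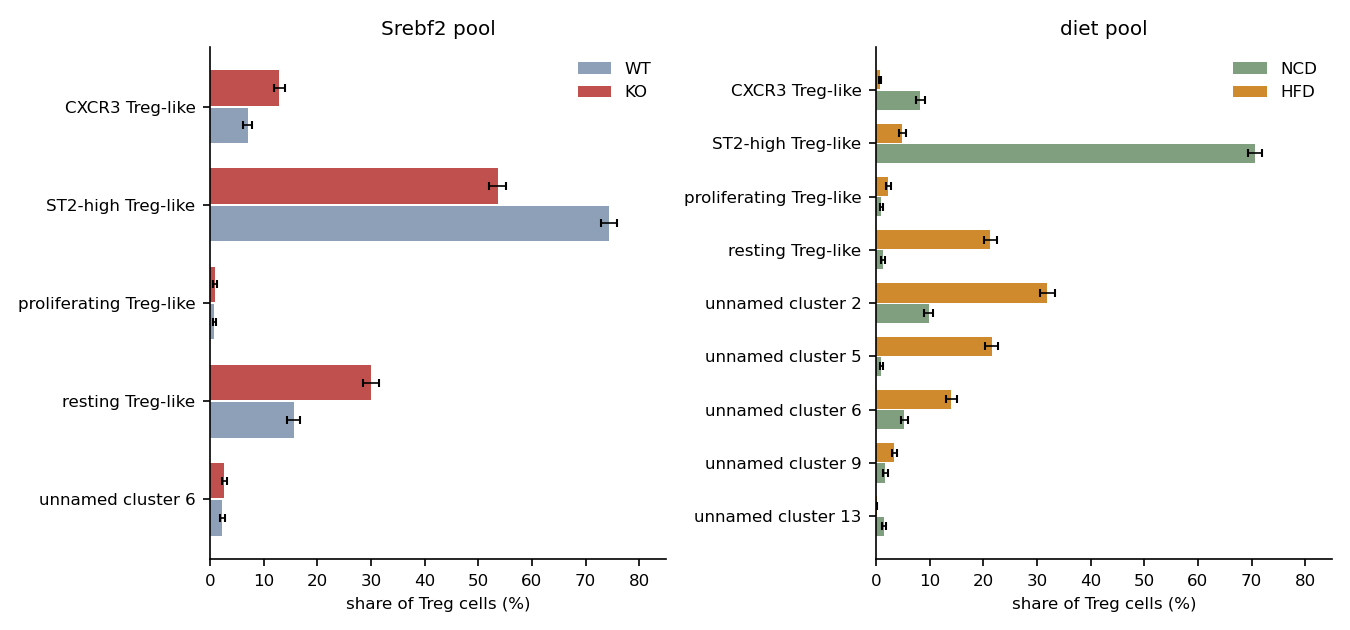
Share of Treg cells (percent) in each named class and each unnamed cluster, for WT and KO on the left and NCD and HFD on the right, with exact 95% binomial intervals as bars. ST2-high-like cells are at 74.4 and 53.7% in the Srebf2 pool and at 70.6 and 4.86% in the diet pool.

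In the diet pool, resting Treg-like cells were at 1.23% of NCD (0.923 to 1.60) and 21.3% of HFD cells (20.1 to 22.5), CXCR3 Treg-like cells at 8.18% (7.39 to 9.03) and 0.691% (0.473 to 0.974), and proliferating Treg-like cells at 0.954% and 2.22%. Unnamed clusters held much of the HFD pool: cluster 2, led by Cxcr3, Ms4a4b and Itgb1, was at 9.77% and 31.9%, cluster 5, led by Il1r2, Tbc1d4 and Lag3, at 0.886% and 21.5%, and cluster 6, led by Ramp3, Isg15 and Tnfrsf9, at 5.22% and 14.0%. The smaller clusters 9 and 13 were at 1.70% and 3.37%, and at 1.41% and 0.0863%. Cluster 13, led by Il5, Cxcl3 and Il13, held 62 NCD and 4 HFD cells. Clusters drawn almost wholly from 1 condition can reflect how that condition was sorted and its depth rather than a cell type, and HFD cells were shallower. The ST2-high-like clusters were led by Egr1, Areg and Atf3 and by Hspa1a, Hspa1b and Txnip. Of these, Egr1, Atf3, Hspa1a and Hspa1b are on the dissociation or early response lists, which were lower in HFD, and Areg and Txnip are on neither. With genes differing 1.5-fold left out of the clustering, ST2-high-like cells were at 77.8% and 23.2% and resting Treg-like cells at 2.48% and 27.5%. CXCR3 Treg-like cells then changed direction, at 14.6% (13.6 to 15.7) and 22.2% (21.0 to 23.4), and proliferating Treg-like cells were at 4.68% and 26.1%. This proliferating Treg-like cluster, of 1417 cells, also had Il1r2 and Penk among its leading genes. Both were leading genes of cluster 5 above, so the 26.1% need not all be dividing cells. The HFD share of ST2-high-like cells was also higher at resolution 1.0 (18.99%), at resolution 0.3 (8.80%), with 200 genes per cell (9.13%) and with 1 Scrublet call removed (9.22%). The main direction for CXCR3 Treg-like cells depends on cluster 2 staying unnamed. After thinning to 2000 UMIs, which left out 232 NCD and 729 HFD cells, an Il1rl1 UMI was found in 67.7% of NCD (66.2 to 69.1) and 14.8% of HFD cells (13.7 to 16.0), or in 78.7% and 18.1% without thinning. B cell-like cells gave 27.0% (21.7 to 32.8) and 9.32% (4.75 to 16.1), at median depths of 8052 and 4480.5 UMIs.

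Within the 3110 NCD and 225 HFD cells of the ST2-high-like class, cholesterol synthesis genes had a median of −0.11 (−0.30 to 0.19), a difference not detectable at this depth. In cluster 1, the larger ST2-high-like cluster, the median was 0.06 (−0.40 to 0.21), and in the unnamed clusters 2 and 6 it was −0.37 (−0.56 to −0.12) and −0.42 (−0.62 to −0.08). Inhibitory receptors were higher in the ST2-high-like class (median 0.81, 0.55 to 0.89), with Pdcd1, which encodes PD-1, at 178 and 781 CPM (2.13) and Btla at 2.87. The Treg core list was at 0.58 (0.42 to 0.68), with Ctla4 at 0.81 and Tnfrsf4 at 0.85, and Tnfrsf9 was at 2.11. The highest ratios in this class were those of Cdkn1c (3.76), Plaur (3.37), Ramp3 (3.202), Palld (3.18), Dgat2 (2.85) and Nyap2 (2.66), each resting on 21 to 50 UMIs in HFD. Among the lowest were Cib2 (−2.31), Hspa1b (−1.74), Lztfl1 (−1.73) and Egr1 (−1.70), with Hbb-bt and Hbb-bs, of which 95.5% and 91.7% of the UMIs of all NCD Treg cells were in 1 cell. Il1rl1 was at 978 and 1108 CPM in this class and Pparg at 82.6 and 41.8 CPM (−0.96). Both genes are among the markers that name the class. The dissociation and heat shock list remained lower (−0.32, −0.42 to −0.26). All of these values can depend on which HFD cells the class holds. It had 427 HFD cells with 1 Scrublet call removed, 880 at resolution 1.0 and 1073 without genes differing 1.5-fold.

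Several HFD values depended on the mix of clusters. With clusters reweighted to the same shares, the cholesterol synthesis median was −0.18, and the log2 ratios of Igfbp4 (−0.31), Ccr7 (−0.10) and Foxp3 (0.03) and the medians of proliferation genes (−0.14) and of fatty acid uptake, storage and oxidation genes (0.08) changed sign. With each cell weighted equally the cholesterol synthesis median was −0.45.

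**Figure D3:**
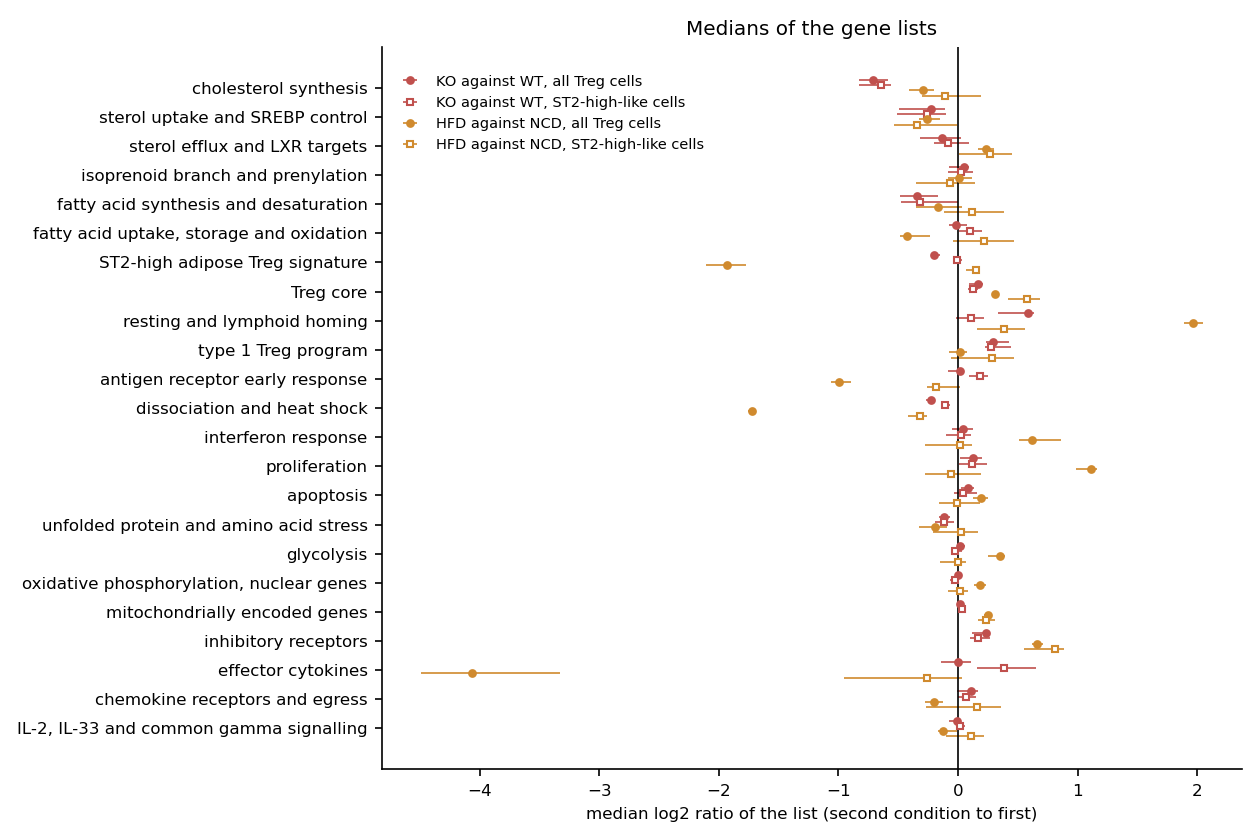
Median log2 ratio of each gene list, KO against WT in red and HFD against NCD in orange, over all Treg cells (filled circles) and within ST2-high-like cells (open squares), with 95% counting intervals as bars. Cholesterol synthesis is at −0.71 in KO and −0.29 in HFD, and the ST2-high signature at −0.20 and −1.93.

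The last comparison set the ratios of both experiments against each other, gene by gene. Among genes higher in both KO and HFD were Gramd3 (1.27 and 2.97), Ccr7 (0.87 and 3.29), Aff3 (0.81 and 3.204), Cd83 (0.83 and 3.11), Lrig1 (0.50 and 3.31) and Tcf7 (0.63 and 3.15), although Ccr7 was at −0.04 in KO with all singlets kept and at −0.10 in HFD with clusters reweighted. Among genes lower in both were Pxdc1 (−1.18 and −3.65), Srebf2 (−4.05 and −0.74), 1700061F12Rik (−0.97 and −3.61), Olfr1259 (−0.50 and −3.92), Ptafr (−0.48 and −3.69) and Bace2 (−0.67 and −3.49). Across 6154 genes the log2 ratios had a Spearman correlation of 0.307 and a Pearson correlation of 0.319. With clusters reweighted to the same shares in each experiment, the Spearman correlation was 0.044 and the Pearson correlation 0.008.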

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

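All 7 values weighed here were chosen as tests after the result they bear on had been seen. Other scalings, reweighting, thinning and clustering without differing genes were planned as alternatives, whereas the values on Apobec3 and the clustering without the dissociation and early response lists were added after seeing the data. With 1 pool per condition none of them measures the spread between mice.

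Apobec3 was lower in KO at a log2 ratio of −3.02, over all Treg cells. Fewer ST2-high-like cells cannot account for it, because the ratio nearest to 0 in any named class with 100 or more cells per condition was −2.64, in CXCR3 Treg-like cells. Apobec3 lies 2.27 Mb from Srebf2 on chromosome 15, and 0.514% of the expressed genes lie as near. A candidate explanation is therefore sequence of another mouse strain carried along with the floxed allele, although the 66 genes within 5 Mb had a median absolute log2 ratio of 0.09 against 0.08 elsewhere, Cbx7 (−1.13) and Poldip3 (0.80) being the farthest from 0 after Apobec3, looked up after their values were seen. Apobec3 was at 0.10 in HFD against NCD, and an effect of Srebf2 loss on Apobec3 itself was not tested.

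Cholesterol synthesis genes were lower in HFD, at a median log2 ratio of −0.29. Scaling to the library total does not account for it, since the highest median over the other scalings was −0.22. With clusters reweighted to the same shares the median was −0.18 (counting interval −0.32 to −0.04), at percentile 3.71 of the random lists. Part of the difference thus remained once the shares of these clusters were evened out. Some clusters came almost wholly from 1 condition, and differing cell states within a cluster stay in the ratio. The value therefore cannot exclude a changed mix of cells as part or the whole of the cause. Within ST2-high-like cells the median of −0.11 and within cluster 1 the median of 0.06 had intervals that span 0. An effect of the diet on these genes stays open as a hypothesis, as does a difference between the mice of the 2 pools.

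ST2-high-like cells were fewer in HFD by −65.8 points, and HFD cells were also shallower. Shallower cells do not account for it, because the share of cells with an Il1rl1 UMI differed by −52.8 points after thinning. The difference was −65.4 points with the dissociation and early response lists left out of the variable genes. Areg, Cxcl2 and Hilpda, which also lead the first of these clusters, are on neither list. That value therefore cannot exclude dissociation and early response as the source of the clusters. Without the genes differing 1.5-fold the difference was −54.6 points. Those genes were left out of the clustering only. The clusters were still named from markers such as Il1rl1 and Pparg, which differ by more than that, so this value is not free of them. How the cells of each diet were isolated, sorted and tagged cannot be separated from the diet, and dissociation genes were lower in HFD within the class too (−0.32). A lower share of ST2-high-like cells in obesity is therefore a hypothesis that these pools do not test.

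In KO, effector cytokines were higher in ST2-high-like cells (median 0.39, 5 measured members) and lower in resting Treg-like cells (median −0.70, 3 measured members), so the classes pointed in opposite directions, and the difference between them was not tested. Markers of conventional CD4 T cells, which share Ifng and Csf2 with this list, were at 0.59 and −0.43 in the same classes. Of the Csf2 UMIs of all KO Treg cells, 22.9% were in 1 cell, a spread that the counting intervals leave out. Barcodes that entered no comparison held signal as well. Only barcodes that passed the gene and mitochondrial filters are counted here. In the Srebf2 pool, Il1rl1 was at 431 CPM in the 300 with neither hashtag and 609 CPM in the 500 with both. In the diet pool it was at 675 CPM in the 767 with neither and 538 CPM in the 579 with both. B cell-like cells held it at 173 CPM in WT, 138 CPM in KO, 232 CPM in NCD and 94.2 CPM in HFD. A Foxp3 UMI was found in 28.8% of these cells in the Srebf2 pool and in 31.6% of the larger such cluster in the diet pool. They may include doublets with Treg cells of the same condition, which was not tested, so these levels are no clean background. B cell-like cells made up 2.60% of WT and 1.18% of KO singlets and 5.41% of NCD and 2.58% of HFD singlets, despite the sort for CD3 and CD4. Macrophage or monocyte-like cells made up 3.04% of NCD and 0.368% of HFD singlets.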

How the results depend on the processing

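Clustering without the dissociation lists and naming by mean marker ratio were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each condition is 1 pool, and leaving out a replicate could not be run for the same reason. Removal of Scrublet calls took out 0 cells in the Srebf2 pool, so for KO against WT that alternative only repeats the main values. The cholesterol synthesis median in KO stayed between −0.74 and −0.67 over 14 alternatives and between −0.70 and −0.63 within ST2-high-like cells; in HFD it stayed between −0.18 and −0.03 within ST2-high-like cells. Over all HFD cells it was −0.45 as the mean of per-cell CPM and −0.18 with clusters reweighted. The ST2-high-like difference in KO was −10.7 points by Il1rl1 after thinning and between −22.2 and −18.9 under the other 12 alternatives. In HFD it was −67.3 with the hashtag share rule, −58.9 with all singlets kept, −55.2 at resolution 1.0, −54.6 without genes differing 1.5-fold and −52.8 by Il1rl1 after thinning. The correlation of both comparisons was 0.268 with all singlets kept, 0.289 for genes at 5 CPM, 0.395 for genes at 100 CPM and 0.044 with clusters reweighted.

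With clusters reweighted, Igfbp4 (−0.31), Ccr7 (−0.10), Foxp3 (0.0285), proliferation (−0.14) and fatty acid uptake, storage and oxidation genes (0.0764) changed sign in HFD. With all singlets kept, Ccr7 in KO (−0.0388) and fatty acid uptake genes in HFD (0.15) changed sign, which adds the cells of other types. Sterol uptake genes within HFD ST2-high-like cells turned positive with 200 genes per cell (0.0582), a 5% mitochondrial limit (0.0933) and Scrublet calls removed (0.0478); the cause was not tested, though the last removes 1 cell and yields other clusters, with 9.22% of HFD cells ST2-high-like. Of the other single genes and lists, 2010 values stayed within their counting interval and 241 moved beyond it. Totals without mitochondrial, ribosomal and receptor genes put the median of all genes in HFD at 0.16, against 0.08 in CPM. The ST2-high-like class of HFD held 884617 UMIs.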

Other observations

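Antigen receptor segments, kept apart from the named genes, were less evenly used in some pools than in others. In KO, Trav7-3 held 15.9% (15.3 to 16.5) of the Trav UMIs and Trav12-2 10.6%, whereas the leading segment in WT, Trav7-5, held 7.72% (7.16 to 8.31). The effective number of Trav segments was 32.2 in WT and 18.4 in KO. In NCD, Trav7-5 held 11.9% (11.4 to 12.5) and Trav4-4-dv10 10.4%, and in HFD the leading Trav4-4-dv10 held 5.14% (4.78 to 5.53), with effective numbers of 17.3 and 42.7. For beta chains the effective number of Trbv segments was 14.1 in WT, 12.3 in KO, 9.95 in NCD and 14.2 in HFD, with Trbv1 at 15.8% of Trbv UMIs in KO and 17.8% in NCD. These are shares of UMIs over a pool of 4 or 5 mice and count no clones.

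In KO, interferon response genes had a median of −0.45 (−0.55 to −0.22) in resting Treg-like cells, with 7 of 13 members lower, and of 0.03 in ST2-high-like cells, and the difference between these classes was not tested. In HFD they were higher over all cells (0.62) but lower within unnamed cluster 6 (median −0.74, −0.94 to −0.48), whose leading genes include Isg15. Penk was higher in HFD ST2-high-like cells as in KO, at 26.7 CPM in NCD and 118 CPM in HFD (2.15).

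Of the 16 marker lists, 7 had enough measured members over Treg cells to give a median and 9 did not, in each comparison. In KO and HFD the medians were −0.20 and −2.49 for ST2-high Treg, 0.63 and 3.15 for resting Treg, 0.85 and 0.02 for CXCR3 Treg, 0.12 and 0.55 for interferon-response Treg, 0.14 and 1.32 for proliferating Treg, 0.30 and −0.34 for conventional CD4 T cells and −0.12 and −4.06 for ILC2. The ILC2 list shares Il5, Il13 and Csf2 with the effector cytokine list. CD8 T or NK-like cells made up 0.658% of WT, 0.551% of KO, 1.61% of NCD and 2.17% of HFD singlets.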
